A study of Xenopus laevis with 12 samples.

How the data were processed

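RNA from animal caps of Xenopus laevis was measured in 12 libraries, wildtype and emi2 mutant at stages 17 and 26, with 3 libraries per group made from caps of different females on different days, per the labels' protocols. Total RNA went into an Illumina TruSeq v2 library, a kit that does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Reads were single, 50 bases long. The text on Cas9 and the guide stands with all samples, so whether wildtype embryos received Cas9 is not stated. Groups were taken from the sample labels.

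The submitters' processing notes name FastQC, STAR, HOMER, Bowtie2 and edgeR, with no versions. Per the file headers, the authors counted reads over the exons of each transcript with HOMER on a Xenbase annotation of genome build 9.2. The deposited signal is a scaled read count: per the file headers, read counts per transcript were multiplied by 1 factor per library with HOMER's simple normalisation, separately for the tables of stage 17 and stage 26. The authors' deposited tables also hold a log2 fold change of wildtype over mutant from edgeR. Per the file headers, edgeR gave the p-value and adjusted p-value of each transcript, with limits of 0.5 on the log2 fold change and 0.1 on the false discovery rate at stage 17, while the stage 26 header breaks off before these options. A core and a non-core list of transcripts were chosen by the authors from the stage 26 comparison by a rule that the sources used here do not give.

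The values of each library were whole multiples of the worth of 1 read, which lay between 0.8945 and 1.092. Within 0.01 read, 100% of values came out whole, and these recovered reads served the count tests. Library totals in the headers lay between 16630000 and 20940000 reads after rounding. The stage 17 table held 65533 transcripts, 74.2% of the 88298 over which the authors' p-values had been adjusted, and 2 of its lines were emptied for this work. The stage 26 table held 16383 (18.6%). It contained all 567 transcripts with an adjusted p of the authors under 1 and 18% of the others, so calls there were enriched by selection. Further transcripts were not analysed here. For that reason the Benjamini-Hochberg adjustment was made over the number of tests that a whole table would hold (20852 at stage 17, 28037 at stage 26, 31588 for the difference). List tests at stage 26 ran on rows from 15916 transcripts held whatever their stage 26 p, called unselected. These were the transcripts with an adjusted p of 1, and 100 of the 567 that lie within the same stretch of the row order of the stage 17 table. Counts of genes cover the held transcripts only. Adjustment over a list alone counted its held members only, so at stage 26 such counts were enriched by the selection of rows.

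The planned test was edgeR's quasi-likelihood test with TMM factors on raw counts. It was run on the recovered reads, with another filter than planned, only after the data were seen. At stage 26 it called 66 genes, against 89 with the main test described next. As the tables hold normalised values, the design's stated fallback was used, limma 3.58.1 with a trend on log2(value + 1), in R 4.3.3, without the replicate number as a block. Genes had to reach a value of 10 in at least 3 libraries, and each was represented by its transcript with the highest mean. The threshold was an adjusted p of 0.05. The difference between stages was planned for raw counts. It was run on these values, in 1 model of all 12 libraries, because the scaling factor of each table cancels within a stage. Tests of the change from stage 17 to stage 26 within a genotype were planned for raw counts only and were not run. Neither was the genotype effect of each stage fitted in 1 model of all 12 libraries. Isoforms share reads, and L and S copies of a gene are near-identical in places, so single copies are uncertain where reads could be split. Injected multicilin RNA can add reads to mcidas.

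Gene lists (19) were fixed before the data were examined: MCC regulators, APC/C, G2 and mitosis, G1/S and replication, centriole, axoneme, intraflagellar transport with BBSome and transition zone, DNA damage response with apoptosis, immediate early and heat shock, Notch, markers of ionocytes, goblet cells, small secretory cells, basal cells, neural tissue, mesoderm with muscle and crest, and endoderm with blood, ribosomal proteins and mitochondrial genes. No mitochondrial gene was held at stage 26. Lists were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over the lists of 1 comparison. LOC identifiers were matched by gene number to a RefSeq table of assembly 10.1, used for names only: 4377 of 17153 LOC rows at stage 17 and 1105 of 4184 at stage 26 had a name. Coordinates are those of the deposited tables.

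Named genes followed a rule fixed before the data were examined. It took fbxo43, then up to 10 called genes per direction with an assigned symbol, a mean of at least 1 CPM and no overlap between groups, ordered by log2 difference. Where under 5 passed, the 5 of smallest p per direction were taken, and from each list up to 4 members of smallest p. For the difference between stages it took the 10 of smallest p. Applying the rule for called genes to the paired calls was added after the data were seen. Genes named beyond the rule are said to be so. Of the paired calls, 1 gene of the DNA damage response list is not reported here.

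The sample titles number the replicates of every group as experiments 1 to 3, and the labels do not state that caps of the same number shared a female or a day. Deviations from the group mean of wildtype and mutant libraries of the same number correlated across genes at 0.63, 0.67 and 0.78 at stage 17 and at 0.55, 0.55 and 0.71 at stage 26, each above the 0.1 set beforehand, so the numbers were taken to pair the samples, and paired values are given where they change a call. The fits that left out a single library were unpaired, and each kept the partner of that library in 1 genotype only. Shifts in them thus mix the genotype effect with differences between replicate numbers.

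The tests of single genes with limma, edgeR and DESeq2 were tried on simulated reads with 200 changed genes. Libraries of the same replicate number were simulated around a shared level. The better recovery of the paired fits was thus built in and is no evidence for the pairing. At stage 17 limma recovered 3% of 2-fold and 53% of 4-fold changes, and 78% and 94% when paired, with 5.5% false calls. At stage 26 these were 2% and 50%, and 78% and 94% when paired, with 3.37% false calls. For the difference between stages limma recovered 0% of 2-fold and 23% of 4-fold changes, and 37% and 76% when paired. The camera test, run once for each stage and once for the difference on simulated reads, called the 1 raised list and 0 of 20 unchanged lists each time. These lists were genes drawn at random, so this trial does not cover lists whose members vary together. Alternatives were other pseudocounts, filters, scalings and feature definitions, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the replicate block, and leaving out each library.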

Results

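RNA was sequenced from Xenopus laevis animal caps, explants of embryonic ectoderm that had been driven towards multiciliated cells (MCCs) by multicilin, the transcriptional co-regulator that starts the MCC programme. Embryos were wildtype or F0 mutants made with Cas9 and a guide RNA against emi2 (fbxo43), an inhibitor of the anaphase-promoting complex (APC/C), the ubiquitin ligase that ends mitosis. Multicilin fused to the glucocorticoid receptor was injected in both genotypes, and dexamethasone switched it on at stage 11 in caps isolated at stage 10. Each library came from 40 caps. The 12 libraries formed 4 groups of 3: wildtype and mutant at stage 17, in mid-differentiation, and at stage 26, when differentiation was complete. Library totals lay between 16630000 and 20940000 reads after rounding. Values below are read counts per transcript scaled by 1 factor per library, given as mean ± SD with n = 3. Log2 differences are mutant minus wildtype on the log2(value + 1) scale, which understates changes of low genes.

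The targeted gene itself was counted in every group, and an edited transcript of an F0 mutant can still be sequenced, so its level does not measure the loss of the protein. At stage 17 the measured row of fbxo43.L (chromosome 6L, 128948768 to 128948914, minus strand, annotation build 9.2) stood at 31.6 ± 14.2 in wildtype and 24.9 ± 4.01 in mutant. That log2 difference of -0.23 (SE 0.42) was smaller than the spread between libraries (limma adjusted p = 1), and it was 0.058 without wildtype replicate 1. The other copy, fbxo43.S (6S, 105330025 to 105341549), had between 0 and 2 reads per library at stage 17. The row of fbxo43.L measured at stage 26 was a longer transcript (6L, 128938929 to 128952056) that was not held at stage 17. The values of the stages are thus not the same measurement. At stage 26 this longer transcript stood at 11.6 ± 9.07 in wildtype and 121 ± 44.4 in mutant, a 10.9-fold higher level (log2 3.45, SE 0.52, limma adjusted p = 0.0303). Recovered reads of that transcript numbered 5, 8 and 21 in the wildtype libraries and 84, 122 and 150 in the mutant libraries. This call was lost under edgeR's quasi-likelihood test, where the log2 difference was 3.34, and on leaving out any of 5 of the 6 libraries, wildtype replicate 3 being the exception.

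The comparison of genotypes at stage 26 asked which transcripts depended on emi2 once differentiation was complete. Genes of the centriole and mitosis lists made up 37 of the 86 genes called higher in mutant caps. The kinase nek2.S, which acts at the centrosome in mitosis, stood at 102 ± 81.6 in wildtype and 2102 ± 737 in mutant. That 23.8-fold difference (log2 4.58, SE 0.47, limma adjusted p = 0.00431) had a log2 value of 5.18 without wildtype replicate 3. Plk4.S, the kinase that starts centriole formation, stood at 49.0 ± 32.2 in wildtype and 965 ± 229 in mutant, 21.6-fold higher (limma adjusted p = 0.00324). Ccna1.L, a cyclin A gene, was 19.5-fold higher in mutant, at 963 ± 358 against 46.5 ± 1.69 in wildtype (limma adjusted p = 0.000458). These are differences between genotypes within stage 26 and not changes from an earlier stage. In all, 89 of the 5311 genes tested passed the threshold, 86 higher and 3 lower in mutant.

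The G2 and mitosis list held 50 tested genes, of which 15 were called, each of them higher in mutant, and 41 were higher adjusted over the list alone. This list also holds nek2.S, which counts among centriole genes too. Cdk1.S, the mitotic kinase, was 16.6-fold higher and its partner cyclin ccnb1.2.S was 6.55-fold higher. The other cyclin A1 copy, ccna1.S, was 12.7-fold higher. On the log2 scale cdk1.S moved from 4.05 to 4.68 without wildtype replicate 3, and ccna1.S from 3.67 to 3.04 without mutant replicate 3. Among the 22 members in unselected rows, held whatever the authors' p, the median log2 difference was 1.07. These 22 ranked above the remaining unselected genes (camera on limma values, adjusted p = 1.1e-14), a call lost with adjusted p = 0.0793 when the correlation between genes was estimated.

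Of 62 tested genes of centriole assembly and amplification, 23 were called, each of them higher in mutant, and 48 were higher adjusted over the list alone. Beside plk4.S they included its scaffold cep152, at 9.11-fold for cep152.L and 11.9-fold for LOC108712907, named cep152.S in the reference. Ccdc67.L, also known as deup1 and a part of the deuterosome on which MCC centrioles form, was 10.4-fold higher. Cep83.L, a protein of the distal appendages, stood at 232 ± 13.0 in wildtype and 1758 ± 288 in mutant (7.50-fold, limma adjusted p = 0.000458). Cep76.L, poc1a.L and the cyclin ccno.S, which is needed for centriole amplification in MCCs, were 16.7-, 13.2- and 11.5-fold higher. The 23 unselected members had a median log2 difference of 0.43, against 1.18 over all 62 tested. Those unselected members ranked above other genes (camera adjusted p = 8.44e-11), which was lost with adjusted p = 0.148 under an estimated correlation.

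**Figure D1:**
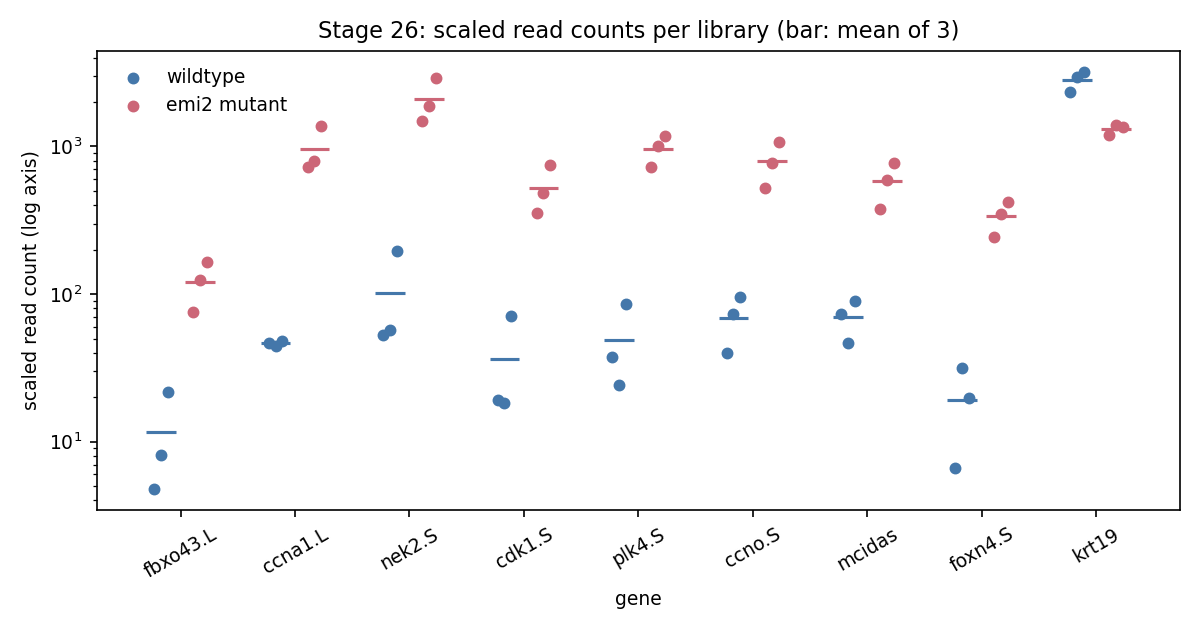
Scaled read counts at stage 26, on a log axis, for 9 genes along the x axis, with 1 point per library (3 wildtype, 3 emi2 mutant) and a bar at each group's mean. For the 8 genes from fbxo43.L to foxn4.S each mutant library lies above each wildtype library, as in ccna1.L with means of 46.5 and 963, while krt19 lies lower in mutant.

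Of 12 tested regulators of the MCC fate at stage 26, 7 were positive and 5 negative. The 4 called, copies of 2 genes, were all higher, and 5 were higher adjusted over the list alone. The multicilin gene mcidas was 8.13-fold higher in mutant and its other copy, LOC108718385 (mcidas.L in the reference), 10.5-fold higher. Reads of the injected multicilin RNA can, however, be counted in either. The forkhead gene foxn4, which acts in MCC differentiation, was higher by 19.2-fold in foxn4.S (log2 4.26, or 3.68 without wildtype replicate 1) and by 3.82-fold in foxn4.L. As a list these regulators did not pass: 7 unselected members had a median of -0.11 (camera adjusted p = 0.303). Among APC/C subunits, activators and inhibitors, 5 of 17 tested genes were called higher and 8 were higher adjusted over the list alone. These were the APC/C activator cdc20.S (4.14-fold), its MCC relative cdc20b.L (9.11-fold), and the ubiquitin-conjugating enzyme ube2c.L (4.01-fold) and ube2c.S (4.50-fold), with the other activator copy cdc20.L (2.72-fold), named after its values were seen. The 9 unselected members had a median of 0.20 (camera adjusted p = 0.0491; adjusted p = 0.643 with an estimated correlation), a call lost without wildtype replicate 1 (0.252) or 2 (0.0943) or mutant replicate 2 (0.0708) or 3 (0.434).

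In the list of G1/S and DNA replication genes, 3 of 19 tested were called, with 7 higher and 2 lower adjusted over the list alone. The called members were the atypical E2F repressors e2f7.L (8.73-fold) and LOC108713138, e2f7.S in the reference (15.4-fold), and the chromatin assembly factor chaf1a.S (4.61-fold). The 14 unselected members had a median of 0.26 (camera adjusted p = 0.145), and passed as higher without wildtype replicate 3 (0.0298). A further gene outside the lists, pgla.S, which encodes a skin antimicrobial peptide precursor, was 11.2-fold higher from a low level (7.11 ± 3.30 to 87.8 ± 28.4).

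Few genes of the cilium itself were called. Dnaaf2.L, which assembles dynein arms, was 1.94-fold higher in mutant, at 4929 ± 446 against 2544 ± 195 in wildtype (limma adjusted p = 0.0187). It was the only call among 41 tested axoneme genes. Of these, 4 were higher adjusted over the list alone, and the 39 unselected members had a median of 0.08 (camera adjusted p = 0.303), passing as higher without wildtype replicate 1 (0.0117). None of 22 tested genes of intraflagellar transport, the BBSome and the transition zone was called, with 3 higher adjusted over the list alone. Its 20 unselected members had a median of 0.15 and passed as a list (camera adjusted p = 0.0491; adjusted p = 0.283 with an estimated correlation). That call was lost on leaving out any library but wildtype replicate 1, with adjusted p between 0.0533 and 0.269. Ribosomal protein genes ranked lower in mutant by a small amount, with a median of -0.10 over 39 genes, 34 of them negative (camera adjusted p = 0.00527; adjusted p = 0.66 with an estimated correlation). They missed the threshold without wildtype replicate 3 (0.321) or mutant replicate 1 (0.106) or 2 (0.261).

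The 3 genes lower in mutant included krt19, a keratin of the outer epidermal layer, at 2839 ± 458 in wildtype and 1316 ± 108 in mutant (log2 -1.10, SE 0.16, limma adjusted p = 0.0251). The others, LOC108696373 (-2.96) and LOC399112, named rgs5.S in the reference (-2.20), were named after their values were seen. Krt19 was the only call among 11 goblet and outer layer markers, whose median of 0.11 and mean of -0.12 differed in sign (camera adjusted p = 0.566, lower); 2 were lower adjusted over the list alone. No call fell among the 3 basal epidermal markers (median -0.32, camera adjusted p = 0.125), of which krt5.7.L was lower adjusted over the list alone. Ionocyte markers (14 genes, median -0.14, camera adjusted p = 0.436), DNA damage response and apoptosis genes (20, median -0.003, 0.436), immediate early genes (11, median 0.18, 0.36) and Notch pathway genes (7, median -0.01, 0.566) had no call, over all genes or adjusted over the list alone. The ionocyte list passed as lower without wildtype replicate 1 (0.0177). For neural, small secretory, mesodermal and endodermal markers 3, 1, 2 and 2 genes were tested, with no call and too few unselected rows for a list test. Adjusted over the list alone, 1 neural gene, ncam1.L, and 1 endodermal gene, gata6.S, were higher.

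With replicate numbers as pairs, 370 genes passed at stage 26, 332 higher and 38 lower, and all 89 calls were among them. The paired calls included 35 of the 50 mitosis genes, 45 of the 62 centriole genes, 9 of the APC/C genes, 5 regulators, 5 axoneme genes, 4 higher and 1 lower replication genes, 3 genes of intraflagellar transport and related complexes, ncam1.L (log2 1.58) and gata6.S (1.16). Dnal4.L (log2 1.53) and bbs12.L (1.80) were among the cilium genes called this way. Lower paired calls included krt12.L (-0.98), krt5.7.L (-0.32), the ornithine aminotransferase gene oat.1.S (-1.97) and apba1.L (-2.38, or -1.71 without mutant replicate 1 and -3.02 without mutant replicate 3). The unpaired count fell to 18 without wildtype replicate 1, to 41 without wildtype replicate 2 and to 27 without mutant replicate 2.

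At stage 17 the question was whether the genotypes already differed in mid-differentiation. No gene passed among 15476 tested with limma, where 279 had an unadjusted p under 0.05. DESeq2 called 5 genes, edgeR's exact test 4 and edgeR's quasi-likelihood test 0. With replicate numbers as pairs 325 genes passed, 223 higher and 102 lower in mutant, and the values below carry that paired test where named. The paired count varied when a pair was left out: it was 278 without pair 1, 948 without pair 2 and 45 without pair 3. Such fits have very few libraries from which to estimate the spread, so their counts are uncertain.

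In the paired fit some genes of the DNA damage response and apoptosis list were called higher in mutant caps. Ccng1.L (chromosome 3L, 17453553 to 17463703), the cyclin G1 gene, stood at 1988 ± 695 in wildtype and 4727 ± 2168 in mutant, 2.32-fold higher (log2 1.21, paired SE 0.08, paired limma adjusted p = 4.09e-09). Cdkn1a.S, the p21 inhibitor of cyclin-dependent kinases, was likewise 2.32-fold higher (paired limma adjusted p = 0.00118). Sesn2.L (log2 0.56) and LOC108717942, sesn1.S in the reference (0.91), also passed when paired and were named after their values were seen. The paired fit called 5 of 45 tested members, all higher, and 8 higher adjusted over the list alone, whereas the unpaired fit called none. As a list the 45 genes had a median of 0.20, with 34 positive (camera adjusted p = 0.00011; adjusted p = 0.899 with an estimated correlation).

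**Figure D2:**
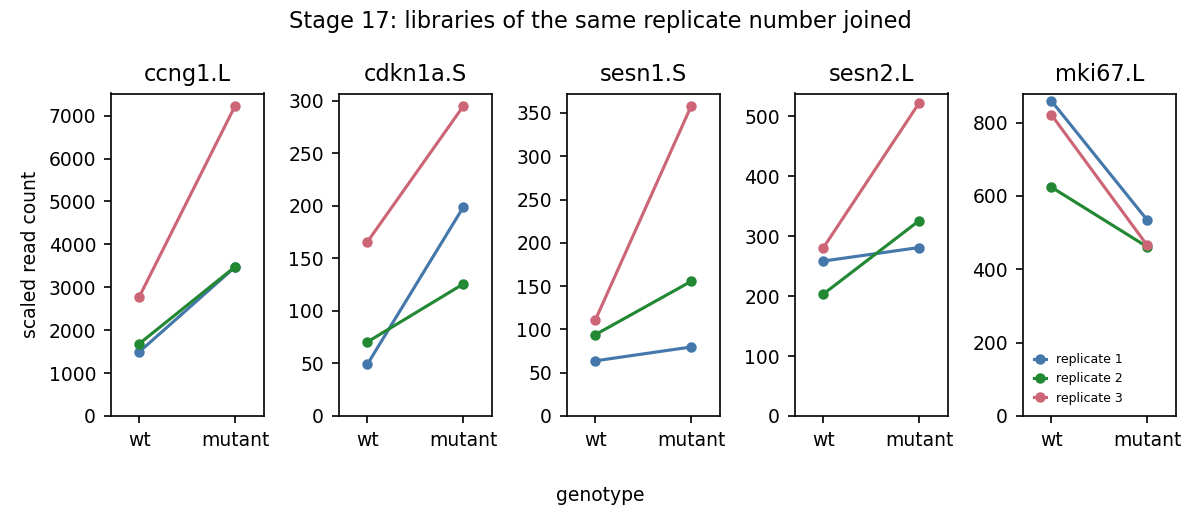
Scaled read counts at stage 17 for 4 DNA damage response genes and mki67.L, wildtype at left and emi2 mutant at right in each panel, with a line joining the libraries of each replicate number. Each line of these 4 genes goes up, as in ccng1.L with means of 1988 and 4727, and each line of mki67.L goes down.

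As a list, genes of G1/S and DNA replication ranked lower in mutant at stage 17 at the preset correlation. Their 70 tested members had a median of -0.24, with 53 negative (camera adjusted p = 0.00011; adjusted p = 0.932 with an estimated correlation). The list missed the threshold without wildtype replicate 3 (0.3) or mutant replicate 1 (0.149). None was called unpaired. When paired, mcm10.L was higher (0.66) and 2 genes were lower, the helicase subunits mcm4.S (-1.42) and mcm6.2.L (-0.73), with 3 higher and 12 lower adjusted over the list alone. Of 96 mitosis genes (median -0.06, camera adjusted p = 0.187) the paired fit called 2 higher and 2 lower. The lower genes were top2a.L (-0.48) and the proliferation marker mki67.L, at 768 ± 127 in wildtype and 487 ± 41.2 in mutant (-0.65, paired limma adjusted p = 0.00118). The mitosis list passed as lower without wildtype replicate 2 (0.0144) or mutant replicate 3 (0.00529). Adjusted over the list alone, 3 mitosis genes were higher and 9 lower when paired. The higher genes were both copies of cyclin A1, ccna1.L (0.76, paired limma adjusted p = 0.000429) and ccna1.S (0.38). Mcm10.L, top2a.L and the cyclin A1 copies were named after their values were seen.

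Centriole genes were close to equal in both genotypes at this stage, with a median of 0.01 over 81 genes, 41 positive and 40 negative (camera adjusted p = 0.888) and no call, paired or not. Single libraries moved this list past the threshold in opposite directions, lower without wildtype replicate 3 (camera adjusted p = 0.000856) and higher without mutant replicate 3 (0.00944). Both fits were unpaired and kept replicate number 3 in 1 genotype only, so differences between replicate numbers enter them. The level of plk4.S was 6927 ± 1879 in wildtype and 6487 ± 1739 in mutant, and nek2.S at 12000 ± 793 and 11870 ± 660. MCC regulators (27 genes, median -0.04, mean 0.02, camera adjusted p = 0.787, lower) and APC/C genes (31 genes, median 0.01, mean -0.03, camera adjusted p = 0.787, lower) had no call either. Intraflagellar transport, BBSome and transition zone genes had a median of 0.04 (71 genes, camera adjusted p = 0.174) and no call. They passed as higher without wildtype replicate 1 (0.00362) or 2 (0.00657) or mutant replicate 3 (0.00245), and as lower without wildtype replicate 3 (0.0444). Axoneme genes passed as a list, with a small median of 0.10 and 109 of 119 members positive (camera adjusted p = 0.00011; adjusted p = 0.932 with an estimated correlation). Without wildtype replicate 3 the axoneme list turned to lower (camera adjusted p = 0.2), and without mutant replicate 1 it missed the threshold (0.228). Paired, 3 axoneme genes were higher, the tektins tekt2.L (log2 0.60) and tekt3.S (0.46) and spef1.L (transcript rna16479, 0.47), and spag1.S was lower (-0.34), the last 2 named after their values were seen. Adjusted over the list alone, 8 were higher and 1 was lower when paired.

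The Notch pathway list was lower at stage 17, with a median of -0.36 over 27 genes (camera adjusted p = 0.0186; adjusted p = 0.906 with an estimated correlation), and missed the threshold without wildtype replicate 3 (0.3) or mutant replicate 1 (0.149). Its paired calls went opposite ways, the target gene hes1.S being higher (0.70) and the feedback inhibitor nrarp.S lower (-0.64), with 1 higher and 7 lower adjusted over the list alone. Mesoderm, muscle and crest markers were higher as a list, with a median of 0.27 over 9 low genes and no call (camera adjusted p = 0.0437; adjusted p = 0.899 with an estimated correlation), a result lost on leaving out any of the 6 libraries (0.0559 to 0.149). Ribosomal protein genes (106, median -0.05) missed the threshold unpaired (camera adjusted p = 0.0974) and passed it when paired (0.0477; adjusted p = 0.841 with an estimated correlation), their 1 paired call being rps9, which was higher (0.32). Unpaired, they passed as lower without wildtype replicate 2 (0.00657) or mutant replicate 3 (0.00349).

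The other lists did not pass at stage 17 with all libraries. Immediate early and heat shock genes had a median of -0.10 over 41 genes (camera adjusted p = 0.163), with the phosphatase gene dusp1.L (-0.53) and myc.L (-1.16, or -1.96 without wildtype replicate 2 and -0.45 without wildtype replicate 3) lower when paired and 1 higher and 11 lower adjusted over the list alone. This list passed as lower without mutant replicate 3 (0.0248). Ionocyte markers had a median of -0.08 over 32 genes (0.187), with dmrt2.L (-1.19) lower when paired, though in 2 of 3 pairs, and 4 lower adjusted over the list alone, and passed as lower without wildtype replicate 2 (0.03) or mutant replicate 3 (0.0426). The log2 difference of dmrt2.L was -1.89 and -0.37 without wildtype replicate 2 and 3, and -0.58 and -1.90 without mutant replicate 1 and 3. Goblet and outer layer markers had a median of -0.09 over 41 genes (0.65), with the claudin gene cldn1.L (-1.85, or -2.57 without wildtype replicate 2) lower when paired and 1 higher and 2 lower adjusted over the list alone. Neural markers had a median of 0.06 over 14 genes (0.888), with myt1.L (-1.09) and sox3.L (-0.46) lower when paired, the same number as adjusted over the list alone. Basal epidermal markers (9 genes, median -0.05, mean 0.06, camera adjusted p = 0.888, lower) had 1 higher paired call, col17a1.L (1.44, or 0.65 without mutant replicate 3). Small secretory cell markers (3 genes, median 0.23, 0.634) had 1 gene higher adjusted over the list alone when paired. Endoderm and blood markers (6 genes, median 0.07, 0.634) and mitochondrially encoded genes (6 genes, median -0.02, 0.888) had no call in either fit.

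Single genes outside the lists with the smallest p at stage 17 were few. LOC101027289, tbx15.L in the reference and a T-box transcription factor, was near 0 in wildtype (0.34 ± 0.59) and stood at 19.5 ± 8.36 in mutant. Zg16.S went from 1.65 ± 1.5 to 39.8 ± 32.2, LOC108714877 from 35.6 ± 6.89 to 132 ± 46.9 and the decoy receptor gene tnfrsf6b.L from 48.3 ± 2.23 to 162 ± 67.1. Ankrd65.L was 3.00-fold higher and nt5c3a.L, a nucleotidase gene, 2.74-fold higher. The log2 difference of zg16.S moved from 3.88 to 3.29 without wildtype replicate 1, and that of nt5c3a.L from 1.46 to 0.85 without mutant replicate 3. The lowest p among lower genes belonged to the chromatin remodeller gene smarca5.S (-0.73), the adhesion molecule gene bcam.L (-1.59), the epiplakin gene eppk1.L (-0.57), the potassium channel gene kcna4.L (-0.89) and LOC108705956 (-0.74). Each of these 11 genes had a limma adjusted p of 1 unpaired and passed when paired, as did the lower genes cdca7.L (-1.72) and foxi4.2.L (-1.29). Among the 5 genes called by unpaired DESeq2 were zg16.S, LOC108714877, tnfrsf6b.L and ankrd65.L. The 4 called by edgeR's exact test were LOC101027289, zg16.S, LOC108714877 and tnfrsf6b.L. Of the stage 17 transcripts 3 had an adjusted p under 0.1 in the authors' deposited table, those of LOC101027289, zg16.S and LOC108714877, all higher in mutant.

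The difference between stages was tested directly, as the genotype effect at stage 26 minus that at stage 17. It passed for 35 of 5883 genes, and in each the mutant excess was larger at stage 26. Among the 10 with the smallest p were the centriole genes cep83.L, cep152.L, ccdc67.L, plk4.S and nek2.S, with differences of 2.88, 3.36, 3.44, 4.53 and 4.59 on the log2 scale, the last being 5.2 without wildtype stage 26 replicate 3. Their stage 17 effects were 0.03, -0.17, -0.05, -0.09 and -0.02. LOC108713138 (e2f7.S), e2f7.L, the checkpoint gene clspn.S and foxm1.S, a transcription factor of mitotic genes, differed by 4.14, 3.31, 3.75 and 3.00, and tcp11l2.S by 1.67. Paired, 196 genes passed, 184 with the larger excess at stage 26 and 12 with the smaller. The count was 20 without wildtype stage 17 replicate 1, 21 without wildtype stage 26 replicate 1, and 22 without replicate 2 of wildtype at either stage or of mutant at stage 17.

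**Figure D3:**
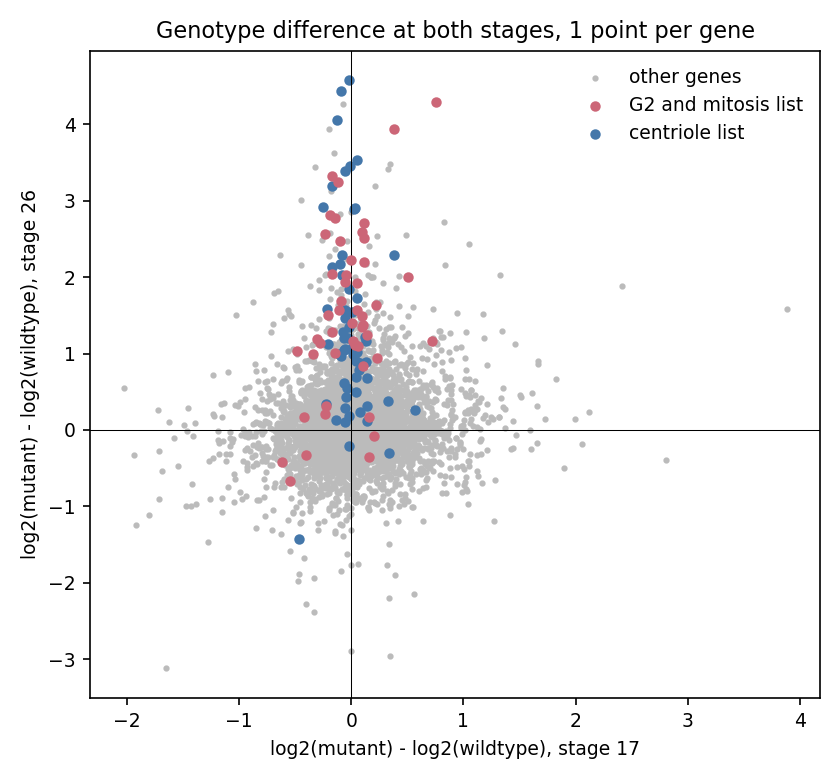
Log2 difference between genotypes (mutant minus wildtype) at stage 17 on the x axis and at stage 26 on the y axis, with 1 point per gene: 59 centriole list genes, 49 G2 and mitosis list genes and 5775 others. Genes of both lists spread upward at stage 26 close to 0 at stage 17, as for plk4.S at -0.09 and 4.44. Part of the points were held because of the authors' stage 26 p, which enriches high values on the y axis. Unselected rows held 27 centriole list genes and 30 G2 and mitosis list genes.

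As lists, mitosis genes showed a larger excess at stage 26 (30 genes, median difference 1.2, camera adjusted p = 1.43e-20), and this held with an estimated correlation (adjusted p = 0.0263). Centriole genes (27, median 0.48, camera adjusted p = 4.42e-07), APC/C genes (11, median 0.52, 0.00321) and replication genes (20, median 0.48, 0.00321) passed in the same direction. The DNA damage response list passed in the other (21, median -0.15, 0.0148). These 4 lists were lost with an estimated correlation (adjusted p of 0.251, 0.476, 0.476 and 0.476). The lists of MCC regulators (0.379), axoneme (0.451), intraflagellar transport (0.451), immediate early (0.095), Notch (0.131), ionocyte (0.544), goblet (0.613), basal (0.451), neural (0.451) and ribosomal genes (0.379) did not pass this camera test, by their adjusted p. Unpaired, no overlap of calls between stages could arise, since 0 of the genes tested at both were called at stage 17 by limma or DESeq2. Paired, 8 genes were higher at both, against 4.17 by chance (4587 genes tested at both, two-sided Fisher's exact p = 0.0676), among them ccna1.L, ccna1.S and nt5c3a.L, and 0 were lower at both.

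The authors' deposited lists of emi2-regulated genes, a core and a non-core list, were chosen on these stage 26 libraries, so their direction there is not independent evidence. All 63 core genes were higher in mutant at stage 26, with 48 called, and 63 higher when paired or adjusted over the list alone. Of 68 tested non-core genes, 43 were called higher and 3 lower, or 62 and 6 when paired, and 68 were called adjusted over the list alone. At stage 17, 54 core genes had a median of -0.03 (camera adjusted p = 0.79) and 47 non-core genes a median of -0.04 (0.422). None was called there unpaired, and 1 gene of each list was higher when paired. In the authors' deposited table of stage 26, 232 of the transcripts held here had an adjusted p under 0.05, 221 higher and 11 lower in mutant.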

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

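The splits of each stage for unpaired calls, the exchanges within pairs for the difference between stages, and the tests on injected multicilin, on library scaling and on Cas9, were chosen only after the results were seen.

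The genotype effect differed between stages for 35 genes by the test of the difference itself. The 10 with the smallest p had log2 differences (stage 26 effect minus stage 17 effect) of 2.88 in cep83.L, 3.36 in cep152.L, 4.14 in LOC108713138, 3.75 in clspn.S, 3.31 in e2f7.L, 3.44 in ccdc67.L, 4.53 in plk4.S, 4.59 in nek2.S, 1.67 in tcp11l2.S and 3.00 in foxm1.S. Among 100 splits of the libraries drawn within each stage, 9 gave as many genes, the real one included, with up to 78 in another split, so chance is not excluded by this count. All 9 kept the real grouping at stage 26, which 10 of the drawn splits had. Without that grouping the highest count was 0, so the count rests on the stage 26 groups whichever way the stage 17 libraries were split. In pairs, 2 of 32 exchanges of genotype within pairs gave as many as the real 196, the real one included, with up to 244 in another, so chance is not excluded by this count either. The 8 exchanges that kept the stage 26 pairs gave at least 133, and the others 0.

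Centriole and mitosis genes were higher in mutant caps at stage 26, 37 of them called. Younger caps as a whole would leave behind the genes still changing near stage 26, in or outside these lists. Rising genes outside these lists lacked a median of 1.14% (quartiles -5.17% and 7.65%) of their log2 change in mutant. Other falling genes lacked 3.83%, against 29.6% for falling list members. With selected rows included these were 1.04%, 6.11% and 36.6%. The typical changing gene outside the lists thus lagged little. Only stages 17 and 26 were sampled, so genes that had levelled off before stage 26 cannot be told from genes still changing. Levelled genes would lack little of their change after a short delay. A short delay of the caps is therefore not excluded by these values. More multicilin from stage 17 on would have raised the list members then, provided they could still respond to more, which was not tested. Yet 31 of the 37 measured at stage 17 had a median log2 difference of -0.0537 and an upper quartile of 0.0413. With limma on recovered reads under TMM, RLE or no factors, at least 29 of the same 37 genes were called, which argues against the library factor as the whole cause. A stage 26 difference in injected multicilin RNA, cutting by Cas9 or injection, and the loss of emi2 itself also stay open. None of these was tested. No group received Cas9 with another guide.

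Only 1 of the 10 splits of the stage 26 libraries gave as many genes, the real one, with 89 calls against at most 0 elsewhere, and only 1 of 10 gave as many lists, with 5 against at most 4. In pairs, 1 of the 4 exchanges within pairs gave as many calls, the real one, with 370 against 0. These splits are too few for a share under 0.05.

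In the paired fit at stage 17, 5 of 45 tested genes of the DNA damage response and apoptosis list were called, all higher in mutant. The paired list test passed at the preset correlation (camera adjusted p = 6.38e-05) and was lost with an estimated one (adjusted p = 0.833). Cutting by Cas9 or injection may raise such genes apart from the loss of emi2, and with 0 groups given Cas9 with another guide these cannot be told apart. A lasting response would keep them high at stage 26, where only 2 of the 5 were measured. These 2 went opposite ways, with a median log2 difference of 0.104. They are too few to decide, although the bound set beforehand for the absence of a lasting response was 0.2.

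At stage 17 all 10 splits of the libraries gave as many unpaired calls as the real one, 0 in each. For lists 6 of 10 splits gave at least the real number of 5, with up to 8 elsewhere. The splits with 8 lists parted only 1 of the 3 pairs, so they also set replicate numbers against each other. The other splits that parted all 3 pairs, as the real one does, gave 1, 5 and 4 lists. In pairs, 1 of 4 exchanges, the real one, gave as many calls, with 325 against at most 0. Again these splits are too few for a share under 0.05.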

How the results depend on the processing

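The tests on recovered reads with TMM, unpaired and with the block, limma on recovered reads with other scalings, the transcript rows, the adjustment over a table alone and the fits without replicate number 3 in both groups or without 1 pair were chosen after seeing the data. Beside fbxo43, given below, all 38 named genes at stage 26 and 10 in the difference between stages kept their direction under every setting run, as did 37 of 41 at stage 17. The exceptions among these 41, plk4.S (-0.34 to 0.15), nek2.S (-0.071 to 0.026, and 0.063 with the replicate block without pair 1), spag1.S (-0.70 to 0.017) and a further spef1.L gene, transcript rna74886 (-0.10 to 0.32), had ranges over left-out libraries that include 0. LOC101027289 and zg16.S had no value at stage 17 on leaving out a mutant library, where they missed the filter. Fits of 12 libraries in 1 model were run for the difference between stages only, and tests of the change with stage within a genotype were not run. Where no cause is named below, the cause was not tested.

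At stage 17 the count of 0 became 325 with the replicate block, 339 with the block in edgeR (310 shared with the former), 5 with DESeq2 and 4 with edgeR's exact test. The block without pair 1, 2 or 3, with very few libraries to estimate the spread, gave 278, 948 and 45. It stayed at 0 in the other settings. At stage 26 the count of 89 became 370 with the replicate block (all 89 among them), 330 with the block in edgeR (314 shared), 66 with edgeR's quasi-likelihood test under TMM, 72 to 86 with limma under TMM, RLE or library totals, 172 with DESeq2 (all 89 among them), 176 with the exact test, 140 with each transcript as its own row, and 183 when adjusted over the table alone, where fewer tests are counted. The block without a pair, again from very few libraries, gave 470, 303 and 259. Leaving out a library gave 18 to 81, with fewer samples; of 31 named calls 10, 18 and 28 held without wildtype replicate 1, 2 and 3, and 27, 16 and 28 without those of mutant. Without replicate number 3 in both groups 76 passed. The difference between stages gave 196 with the block, 82 with DESeq2, 81 with the likelihood ratio test and 72 adjusted alone, and 20 to 45 without a library. The overlap was 8 with the block. The block changed no other list test at either stage or in the difference. Of the counts adjusted over the list alone at stage 26, it made that of MCC regulators 6 higher and 1 lower, APC/C 10 higher, mitosis 42 higher, replication 9 higher and 3 lower, centriole 50 higher, axoneme 5 higher, goblet 3 lower and neural 2 higher.

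For fbxo43.L at stage 26 the log2 difference was 3.34 with TMM and 3.34 with RLE factors, both short of the threshold, and 3.01 to 4.01 without a library. It had no value without replicate number 3 in both groups, where it missed the filter. At stage 17, on the shorter row held there, it ran from -0.64 to 0.058 without a library, turning sign without wildtype replicate 1. At stage 26 it stayed positive under every setting run that gave a value. The authors' core and non-core lists had 1 and 1 members called at stage 17 with the block.

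The number of lists past the threshold (5 at each stage) was 0 with an estimated correlation and 0 with fry at stage 17, 3 with no filter, and 1 to 10 without a library. At stage 26 it was 0 with an estimated correlation, 3 with fry, 3 with no scaling and 2 to 6 without a library. With no filter on low values lists turned direction for centriole (adjusted p = 0.728), small secretory (0.464), neural (0.886), mesoderm (0.838) and endoderm genes (0.14) at stage 17 and for DNA damage response genes at stage 26 (0.788). Leaving out single libraries turned some lists at stage 17, whose camera adjusted p then ranged from 0.382 to 0.959 for MCC regulators, 0.116 to 0.95 for APC/C, 0.000856 to 0.471 for centriole, 6.05e-09 to 0.228 for axoneme, 0.00245 to 0.825 for intraflagellar transport, 0.03 to 0.877 for ionocyte, 0.0811 to 0.788 for goblet, 0.2 to 0.959 for small secretory, 0.727 to 0.959 for basal, 0.448 to 0.891 for neural, 0.0713 to 0.959 for endoderm, 0.00349 to 0.785 for ribosomal and 0.431 to 0.905 for mitochondrial genes. At stage 26 they were 0.111 to 0.719 for immediate early and 0.0177 to 0.803 for ionocyte genes. Fbxo43.S had between 0 and 2 reads per library at stage 17, too few to test.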

Other observations

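The test on the wildtype fall was set before its result was seen, and the description of the course was added after the data were examined. Stages were compared on recovered reads per library total, over genes held in both tables. Most genes called higher in mutant caps at stage 26 had fallen from stage 17 to stage 26 in wildtype. Of the 86 called higher, 72 were held in both tables, and 61 of these (84.7%) had fallen at least 4-fold in wildtype, 33 of them outside the centriole and mitosis lists. The 72 had a median log2 change of -4.16. Among 5658 unselected genes 9% had such a fall. In 100 simulated sets with no genotype effect the share was at most 18.1%. The call and the fall share the wildtype stage 26 values. From each simulated set the genes with the largest mutant excess were taken, without the limma test that the real calls passed. These sets thus only approximate what the shared values alone give. They hold no genes with a true mutant excess, so they do not test its cause. A candidate explanation is that transcripts of mid-differentiation fell incompletely in mutant. This is a hypothesis drawn from the libraries that showed the difference, and it was not tested on others.

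Among unselected rows, falling members of the centriole and mitosis lists (29 genes) fell by 3.72 on the log2 scale in wildtype, and mutant lacked a median of 29.6% of that fall (quartiles 13.2% and 40.6%). For 480 other falling genes the median was 3.83% (quartiles -3.56% and 10.9%). For 552 rising genes it was 1.14%. With selected rows included, the medians were 36.6% for 74 falling list members, 6.11% for 560 other falling genes (upper quartile 17.6%) and 1.04% for 564 rising genes. Simulated libraries with no genotype effect gave 0.52%, 1.1% and 1.9% for the 3 unselected sets.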
